A study of Passer montanus with 72 samples.

How the data were processed

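RNA was measured by sequencing in 3 brain regions of 24 Eurasian tree sparrows (Passer montanus) that were caught in the wild and kept in captivity. The labels give 11 females and 13 males, and each bird gave 1 library from caudal hippocampus, 1 from rostral hippocampus and 1 from striatum, 72 libraries in all. The series design text names the caudal part dorsal hippocampus; the word caudal, from the sample labels, is used here. The behaviour named in the series title is not given per bird in the labels, so no comparison by neophobia was made.

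Per the labels' protocols, RNA was extracted with a lipid tissue kit and libraries were made and sequenced by a service company. Per the submitters' processing notes, HISAT2 and StringTie were used, with no version named. The strand setting, the counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene for 21957 genes, not normalized. None of its gene identifiers was in the Passer montanus reference table (0 matched), while 12417 gene symbols were, and 34 gene descriptions name Taeniopygia guttata, the zebra finch. Reads of a sparrow counted on another species' gene models would be lost where the sequences differ, so levels of different genes within a library are not comparable in absolute terms. Symbols, identifiers and positions are those of the deposited table. In 7258 genes no library had a count. The 13 mitochondrial protein genes held 17 counts over all libraries, so they were not analysed here, and no row lacked a gene name. Without a known strand setting, overlapping and antisense genes and near-identical copies cannot be told apart by these counts.

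Total counts ranged from 2629433 to 5323201 per library (median 4071234). Within every group, pairs of libraries differed by more than sampling noise (lowest chi-square per degree of freedom 5.87), so none was counted as a duplicate.

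Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All adjusted p-values of single genes below come from this test unless another is named, and errors of log2 folds are standard errors. The 3 regions of a bird are not independent, so bird was a block in the region comparisons and the sex by region interactions, over all 72 libraries. The pairing comes from the bird numbers in the labels. The median correlation of a bird's deviations was 0.176 between the hippocampal parts, 0.130 between caudal hippocampus and striatum, and 0.155 between rostral hippocampus and striatum, against -0.0254, -0.0122 and -0.0121 for different birds. Sexes were compared in each region separately, 1 library per bird. A further F test asked which genes differed among birds of one sex at a level shared by the 3 regions. Striatum was compared with the mean of both hippocampal parts.

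In birds, males carry a pair of Z chromosomes and females a Z and a W. A sequence was taken as Z when at least 3 genes of a fixed list of Z genes lay on it, which gave 1084 genes and held 131 of the 134 listed genes found. The rule fixed for the W asked for a sequence named W and gave none; the sequence that carries CHD1W, with 165 genes, was taken as the W sequence after the data had been seen. Z-linked level per library was the mean log2 CPM (counts scaled to a common library total) of Z genes minus that of other genes, compared by a two-sided permutation test with 100000 resamples.

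The designs, the 16 gene lists and the rule for naming genes were set before the data were examined. The lists were striatal medium spiny neuron, pallial glutamatergic neuron, GABAergic interneuron, oligodendrocyte and myelin, astrocyte, microglia and macrophage, vascular and meningeal, ependyma and choroid plexus, erythrocyte, immediate early genes, monoamine receptors and transporters, glucocorticoid and stress axis, sex steroid signalling, glutamate and GABA receptors, opioid and endocannabinoid genes, and Z-linked genes. Genes were matched by symbol, from 55.6% of the erythrocyte list to 100% of the medium spiny neuron list. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. List p-values are camera's, adjusted over the lists of a comparison, unless another is named. Genes named are 8 fixed receptors and enzymes, the 8 with the largest change per direction among genes with a symbol, a mean CPM of at least 1 and, for regions, the same direction in at least 20 birds, the 6 Z genes with the smallest p per sex comparison, up to 4 called members per list, and the 5 with the smallest p in each interaction and in the bird test. Some genes that this rule takes are not reported here.

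The same steps were tested on simulated data in which 200 genes were changed. The spread of the simulated counts was estimated over all libraries of a fit, without region, sex or bird terms. Differences between regions thus entered as spread in the fits of 72 libraries, and no bird effect was simulated for the comparisons below. The shares recovered hold for that setting and may differ from those in the real fits. For caudal against rostral hippocampus 44.8% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered. For the sex comparisons, 4-fold changes were recovered in 93.9%, 95.5% and 95.5% of genes in caudal hippocampus, rostral hippocampus and striatum, and 1.5-fold changes in 52.2%, 56.7% and 46.3%. For the interaction of the hippocampal parts only 4.48%, 41.8% and 60.6% were recovered at 1.5-fold, 2-fold and 4-fold. Alternatives were no block, DESeq2 1.42.0 and its size factors, limma voom, no filter on low counts, separate fits, bird as a random effect, birds 1 to 22 alone, a myelin covariate, and each bird left out in turn. Figures were drawn with matplotlib 3.10.9.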

Results

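The data are counts per gene in 72 libraries, 24 each from caudal hippocampus, rostral hippocampus and striatum, of 11 birds labelled female and 13 labelled male. Total counts ranged from 2629433 to 4461916 in caudal hippocampus, from 3422268 to 5323201 in rostral hippocampus and from 3319685 to 4895476 in striatum. The first principal component held 32.7% of the variance and separated striatum from hippocampus, and the second held 10.8%. The striatum library of bird 11, a male, stood apart, with a count in 7718 genes, the fewest of all libraries; the most was 11547.

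**Figure D1:**
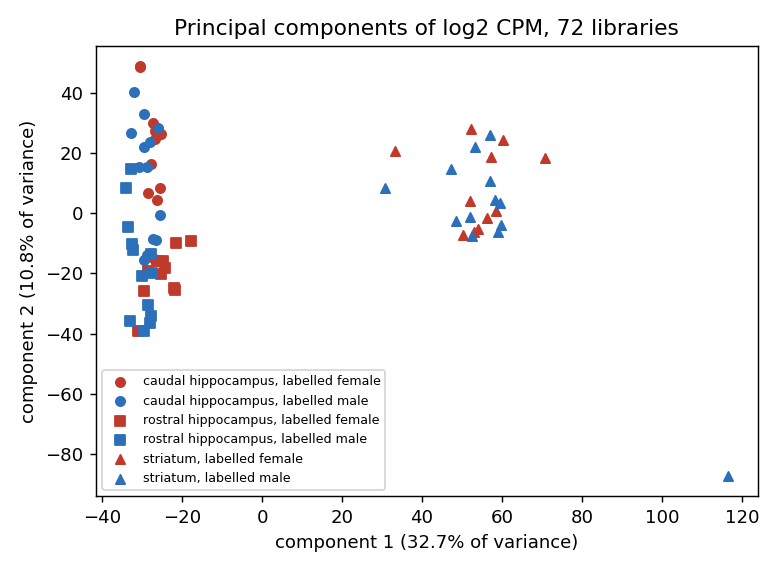
Each point is 1 of the 72 libraries, placed by its first (32.7% of variance) and second (10.8%) principal component of log2 CPM, with shape for region and colour for the sex label. Striatum lies to the right of both hippocampal parts, and the single point at the lower right, at 116 on the first component, is the striatum library of bird 11.

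The sex labels were compared with the counts of the W sequence. The 10 other birds labelled female had mean W CPM of 2071 ± 118 in caudal hippocampus, 2073 ± 110 in rostral hippocampus and 1959 ± 145 in striatum (SD, n = 10), and males had 30 ± 8.23, 31.3 ± 6.44 and 23.6 ± 10.3 (SD, n = 13). The 3 libraries labelled female of bird 260 had 26.6, 28.0 and 22.96 and no count of CHD1W, where the other females had 101 to 216 and males at most 3. The counts thus go against the label of bird 260. It stayed in the group its label gives, and every direction between the sexes below is drawn with the libraries labelled female of bird 260 among the females.

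**Figure D2:**
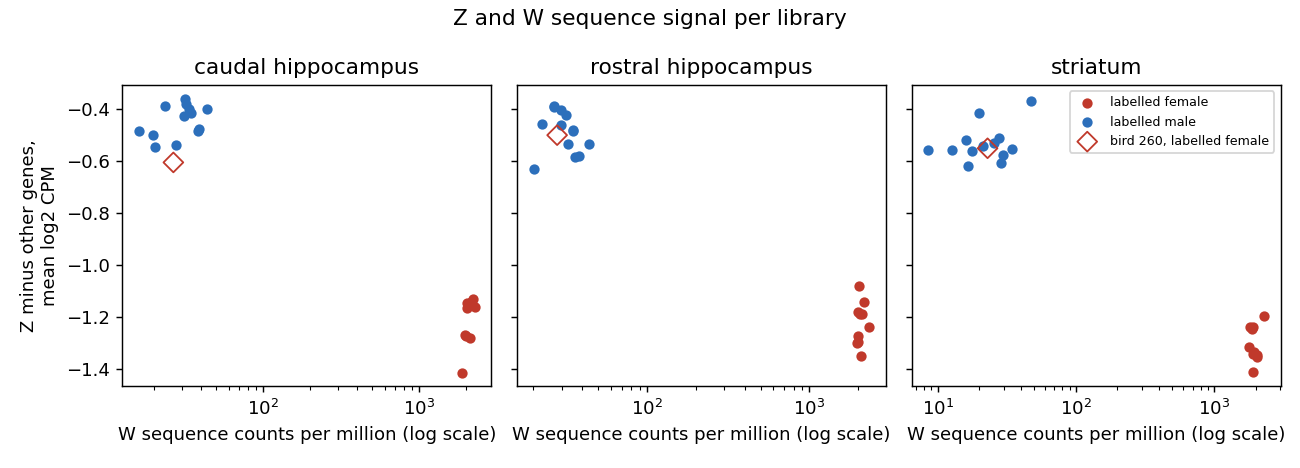
Each point is a library; the horizontal axis is W sequence CPM on a log scale and the vertical axis the mean log2 CPM of Z genes minus that of other genes. Bird 260, labelled female (open diamond), lies at 26.6, 28.0 and 22.96 W CPM, while the other birds labelled female lie between 1779 and 2331.

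Striatum and hippocampus were compared to describe what sets the regions apart. Genes of striatal medium spiny neurons, the projection neurons of the striatum, were higher in striatum. DRD2, a dopamine receptor, rose from 1.39 CPM in hippocampus to 118 ± 34.7 in striatum (SD, n = 24), a log2 fold of 6.39 ± 0.17 (adjusted p = 7.13e-38). Genes of pallial glutamatergic neurons were lower: NEUROD1, a transcription factor of such neurons, went from 58.8 to 0.602 ± 1.96 CPM (SD, n = 24), a log2 fold of -6.80 ± 0.28 (adjusted p = 9.74e-29). Of 10445 genes tested, 6537 changed, 3083 higher and 3454 lower in striatum, and 1716 of them by a log2 fold of at least 1 (641 higher, 1075 lower).

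Of 29 medium spiny neuron genes tested, 27 rose and 2, RARB and SP8, fell (27 and 2 adjusted over the list alone), with a median log2 fold of 3.07 (camera adjusted p = 5.8e-48). ISL1 (8.37), TAC1 (5.61), PDE10A (4.52), ADCY5 (4.02) and DLX6 (3.68) were among them, as was the dopamine receptor DRD1 (3.07 ± 0.07). Of 29 pallial glutamatergic genes 22 fell and 6 rose (22 and 6 adjusted over the list alone; median -2.09, camera adjusted p = 1.12e-14). SLC17A6, a vesicular glutamate transporter, was at -4.48, NEUROD2 at -5.79, NRN1 at -4.98 and ZBTB18 at -2.73, while CCK (1.49), KCNA1 (1.57), GRM5, GRIN2B, CAMK2A and ZBTB20 rose. Of 18 GABAergic interneuron genes 12 rose and 4 fell (12 and 4 adjusted over the list alone; median 1.29, camera adjusted p = 1.72e-07). The GABA transporter gene SLC32A1 (2.11), GAD2 (1.73) and LAMP5 (1.74) rose, and SST, the gene of somatostatin, fell (-3.59). The cholinergic genes CHAT (7.29) and SLC18A3 (6.45) and the transcription factor LHX8 (6.07) were among the largest rises, with SKOR1 (7.45), MME (6.89) and IL16 (6.68). BDNF (-5.70), NEUROD6 (-6.60), C1QL3 (-6.04), UTS2B (-6.54), RLBP1 (-6.70) and POSTN (-5.76) were among the largest falls.

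**Figure D3:**
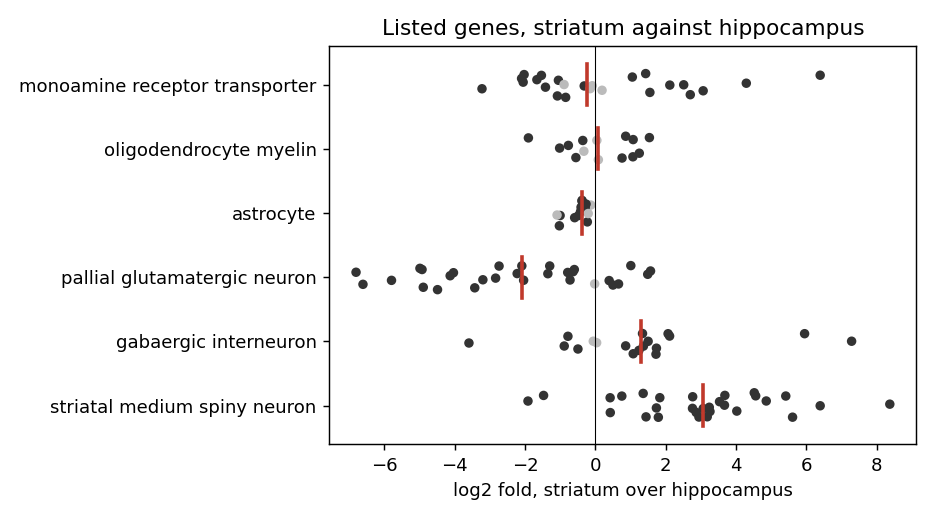
Each point is a gene of 1 of 6 fixed lists, placed by its log2 fold of striatum over hippocampus; dark points passed an adjusted p of 0.05 and red lines are list medians. The medium spiny neuron list has a median of 3.07 and the pallial glutamatergic list one of -2.09.

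Receptors for dopamine and other monoamines moved apart. Of 24 monoamine genes 9 rose and 11 fell (9 and 11 adjusted over the list alone); the median was -0.23 while the mean was 0.29 and camera gave a rise (adjusted p = 0.000981), so median and test differ in sign. DRD5 (4.29), ADRA2C (2.70), HTR1B (2.51) and HTR2A (2.12) rose, and HTR2B (-3.22) and ADRA1B (-2.02) fell. Of 10 opioid and endocannabinoid genes 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.268). The opioid peptide genes PDYN (5.41) and PENK (3.67) and the receptor OPRK1 (1.44) rose, while CNR1, a cannabinoid receptor, fell (-1.18). Of 30 glutamate and GABA receptor genes 11 rose and 12 fell (11 and 12 adjusted over the list alone; median -0.05 while mean and camera were positive, camera adjusted p = 0.927), with GABRA5 (3.09) and GRM4 (2.11) higher and GABBR2 (-1.42) lower. Of 17 stress axis genes 5 rose and 11 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.113): SGK1 (1.24), HSP90AA1 (0.65) and the glucocorticoid receptor NR3C1 (0.58 ± 0.07) rose, and ADCYAP1 (-4.18), ZBTB16 (-1.99) and the mineralocorticoid receptor NR3C2 (-0.32 ± 0.07) fell. Of 10 sex steroid genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.707). CYP19A1, the enzyme that makes oestrogens, was at -2.93 ± 0.38, ESR1 at -3.29 ± 0.52 and GPER1 at -1.62, and NCOA2 rose (0.26). Of 22 immediate early genes 5 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.113), with HOMER1 (0.75) and EGR1 (0.47 ± 0.09) higher and NR4A2 (-1.45) and NR4A3 (-1.12) lower.

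Glial and other cell type genes also differed between striatum and hippocampus. The myelin genes MBP (1.54) and UGT8 (1.07) rose and TF fell (-1.90); 6 of 14 oligodendrocyte genes rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.707). None of 14 astrocyte genes rose and 11 fell (0 and 11 adjusted over the list alone; camera adjusted p = 0.094), with FABP7 at -1.0, AGT at -0.42, GLUL at -0.40 and SLC1A2 at -0.38. Of 13 ependyma and choroid plexus genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.702): TTR at -5.38, OTX2 at -3.57, AQP1 at -1.81 and KL at -1.57. Of 5 erythrocyte genes 4 fell, among them the globins HBAA (-2.05) and HBAD (-1.03), with SLC4A1 (-1.20) and TAL1 (-1.02) (0 and 4 adjusted over the list alone; camera adjusted p = 0.382). Of 20 vascular and meningeal genes 3 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.570), and of 6 microglial genes CSF1R fell (-0.43), which did not hold when adjusted over the list alone (0 and 0, camera adjusted p = 0.707). The call of CSF1R was also lost in 7 of 33 alternatives, 4 of them with a bird left out. Of 119 listed Z-linked genes 36 rose and 32 fell (36 and 32 adjusted over the list alone; camera adjusted p = 0.707; median 0.02 while mean and test were negative). The camera calls of this comparison, for the medium spiny neuron, pallial, GABAergic and monoamine lists, held with an estimated correlation.

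Caudal and rostral hippocampus differed less. The largest rise in the caudal part was TTR, the thyroid hormone carrier transthyretin that choroid plexus makes in quantity (gene identifier 100190720, positions 107705997 to 107714203 of its sequence in the build of the deposited table), at 547 ± 858 CPM against 0.989 ± 1.80 (SD, n = 24), a log2 fold of 8.57 ± 0.61 (adjusted p = 6.32e-16). Receptors for opioids and cannabinoids were lower in the caudal part: OPRM1, the mu opioid receptor, was at 10.8 ± 5.61 CPM against 30.97 ± 9.50 (SD, n = 24), a log2 fold of -1.54 ± 0.14 (adjusted p = 2.92e-12). The transcription factors SIX3 (2.99), DBX1 (2.72) and DACH2 (2.22) and the genes CYP19A1 (2.62 ± 0.35), COL2A1 (2.49), HS3ST2 (2.30) and ACKR3 (2.25) were higher in the caudal part. SRL (-2.52), the adenosine receptor ADORA2A (-2.42), CAMK1G (-2.23), ADAMTSL1 (-1.96), ST8SIA5 (-1.89), PLCXD3 (-1.85), HS6ST3 (-1.83) and SFRP4 (-1.81) were lower. In all 4765 of 10445 genes changed, 2412 higher and 2353 lower in the caudal part, and 438 by a log2 fold of at least 1 (237 higher, 201 lower).

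Of 10 opioid and endocannabinoid genes 1 rose and 6 fell in caudal hippocampus (1 and 6 adjusted over the list alone; median -0.76, camera adjusted p = 9.32e-05, held with an estimated correlation, adjusted p = 0.00735). OPRK1 (-1.78), OPRL1 (-1.71) and CNR1 (-1.33) fell with OPRM1. Of 24 monoamine genes 2 rose and 11 fell (2 and 11 adjusted over the list alone; median -0.59, camera adjusted p = 0.0141; adjusted p = 0.0834 with an estimated correlation). The adrenergic receptors ADRA1B (-1.56) and ADRA2A (-1.38) and the serotonin receptor HTR1B (-0.63) fell, while DRD1 (-0.07 ± 0.09, adjusted p = 0.563) and DRD2 (-0.61 ± 0.32, adjusted p = 0.108) did not pass; DRD2 passed with limma voom and without bird 7. Of 13 ependyma and choroid plexus genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.87, camera adjusted p = 0.0436; adjusted p = 0.263 with an estimated correlation), with OTX2 (4.12), AQP1 (1.77) and FOXJ1 (1.75) higher and PROM1 (-0.65) lower; with that list as a covariate, chosen after seeing the data, OTX2 turned to -1.07. Of 10 sex steroid genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.586). ESR1, an oestrogen receptor, rose by 2.42 ± 0.45 and SRD5A2 by 1.48, and GPER1 fell (-1.0). The calls of ESR1, SRD5A2, GPER1, TTR and AQP1 between the hippocampal parts were each lost in 1 alternative.

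The pallial, medium spiny neuron, GABAergic and glutamate and GABA receptor lists did not pass camera between the hippocampal parts. With fry the pallial (adjusted p = 0.00205), GABAergic (adjusted p = 0.000737) and glutamate and GABA receptor lists (adjusted p = 1.24e-05) passed, all with negative medians. Unlike camera, fry does not set a list against the other genes, and 45.6% of all tested genes were called here. The astrocyte (fry adjusted p = 0.000851) and microglial lists (fry adjusted p = 0.00255), among others, passed fry too. The medium spiny neuron list did not pass fry (adjusted p = 0.354). Of 29 pallial glutamatergic genes 2 rose and 13 fell (2 and 14 adjusted over the list alone; camera adjusted p = 0.0651): PROX1, a factor of dentate granule cells in mammals, rose (1.28 ± 0.17) and CAMK2A (-0.75), GRIN2B (-0.68) and ETV1 (-0.64) fell. Of 29 medium spiny neuron genes 5 rose and 9 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.693), with MEIS2 (0.65) and ARPP21 (0.54) higher. Of 18 GABAergic genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.307): GAD1 (-0.71), GAD2 (-0.49) and ADARB2 (-0.89) fell. Of 30 glutamate and GABA receptor genes 5 rose and 13 fell (5 and 13 adjusted over the list alone; camera adjusted p = 0.0651), among them GRIK3 (-0.87), GRIN2A (-0.70) and GRIA1 (-0.70). Of 22 immediate early genes 4 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.307), with JUN (0.36) higher, DUSP5 (-1.02) and DUSP6 (-0.47) lower and EGR1 at -0.02 ± 0.10 (adjusted p = 0.882). Of 17 stress axis genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.930): FKBP5, a glucocorticoid-responsive co-chaperone, rose (1.21 ± 0.12), as did ADCYAP1 (0.81), while its receptor ADCYAP1R1 fell (-1.22 ± 0.22). NR3C1 (-0.20 ± 0.09, adjusted p = 0.0531) and NR3C2 (-0.12 ± 0.08, adjusted p = 0.258) did not pass, though NR3C1 passed in 10 of 33 alternatives, among them those without bird 2, 3, 7, 11, 16, 17 or 20.

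Among glial lists, 2 of 14 astrocyte genes rose and 7 fell in caudal hippocampus (2 and 7 adjusted over the list alone; camera adjusted p = 0.0651), with SLC1A3 (-0.79), GJA1 (-0.46) and SLC1A2 (-0.46) lower. Of 14 oligodendrocyte genes TF rose (0.67) and PDGFRA (-0.36) and ASPA (-0.42) fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.929). TF turned to -0.96 with the choroid plexus covariate, an alternative chosen after seeing the data, and its call was lost without bird 2, 12 or 20 and with the hippocampal libraries alone. Of 20 vascular and meningeal genes 2 rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.817), with RGS5 (-0.88) and CLDN5 (-0.88) lower. Of 6 microglial genes 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.400). No erythrocyte gene of 5 changed (0 and 0 adjusted over the list alone; camera adjusted p = 0.927; the median was -0.16 while the mean and camera were positive). Of 119 listed Z-linked genes 23 rose and 37 fell (26 and 37 adjusted over the list alone; camera adjusted p = 0.307).

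The sexes were compared in each region because the series title sets males and females side by side. Genes on the Z sequence were higher in males in all 3 regions. The median log2 fold of males over birds labelled female was 0.70 in caudal hippocampus (383 genes), 0.67 in rostral hippocampus (406 genes) and 0.66 in striatum (393 genes), which is 1.62-fold, 1.59-fold and 1.58-fold, and 96.6%, 93.6% and 95.2% of the genes were higher in males. The permutation test of the level per bird gave p = 1e-05 in each region, the smallest it can give (1e-05 adjusted over the 3 regions, each with and without bird 260). In caudal hippocampus 190 Z genes rose in males, in rostral hippocampus 208 and in striatum 137, and none fell. Of 365 Z genes tested in all 3 regions 100 rose in all 3 and 327 (89.6%) were higher in males in all 3. UBAP2 (1.18 ± 0.12), DMXL1 (1.13), NAA35 (1.11), MPDZ (0.98), ECPAS (0.81) and RIC1 (0.62) had the smallest p in caudal hippocampus, MRPS27 (1.61 ± 0.20), CZH9orf64 (1.53), SMAD2 (0.96), ANKRA2 (0.90), SMARCA2 (0.87) and SPIN1 (0.84) in rostral hippocampus, and PPWD1 (1.11 ± 0.13), DNAJA1 (1.07), PAIP1 (1.05), MTREX (0.99), SLC30A5 (0.86) and NIPBL (0.83) in striatum. Without bird 260 the medians were 0.77, 0.74 and 0.75. Of the listed Z-linked genes 60 of 107, 58 of 112 and 43 of 108 rose and 0 fell (84, 80 and 74 rose adjusted over the list alone, where 1 fell in rostral hippocampus), with camera adjusted p = 4.61e-76, 1.43e-45 and 4.58e-100, and adjusted p = 1.3e-07, 0.00027 and 3.05e-08 with an estimated correlation.

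In caudal hippocampus TTR was the gene with the largest sex difference outside the sex chromosomes. Males had 995 ± 968 CPM (SD, n = 13) and birds labelled female 18.0 ± 23.7 (SD, n = 11), a log2 fold of 5.83 ± 0.93 (adjusted p = 0.000141). The counts of TTR ranged from 5 to 10470 in males (median 2295) and from 5 to 177 in birds labelled female (median 17). ACKR3 (2.33), a chemokine receptor, the secreted superoxide dismutase SOD3 (2.12), TF, the iron carrier transferrin (1.58), UTS2B (1.35), the dopamine receptor gene D1DR (1.20), SEMA3F (1.12) and ADAMTS15 (0.94) were also higher in males. OMA1 (-0.55), ACBD7 (-0.54), TMSB4X (-0.52), DNER (-0.45), ALG12 (-0.42), KBTBD8 (-0.42), ZFAND4 (-0.40) and CRKL (-0.37) were lower. The calls of KBTBD8, ACBD7, OMA1, UTS2B and ZFAND4 were lost in 27, 24, 23, 20 and 17 of 33 alternatives, and those of the other genes named here in at most 9. In all 238 of 8846 genes changed: 190 on the Z sequence, 6 on the W sequence, all lower in males, and 42 others, of which 17 were higher and 25 lower in males. Only 7 of the 165 genes on the W sequence passed the filter on low counts here, against 36 in the fit of all libraries. The filter asks for the minimum count in as many libraries as the smaller group holds, here 11. Bird 260, labelled female, had 0 CHD1W counts where the 10 others had 101 to 159. A gene that reached the minimum only in those 10 females could not pass, in this or the other regions. The 6 are therefore no count of all W genes that differ by sex. With scaling factors from genes outside the sex chromosomes the split of the other genes was 26 higher and 16 lower.

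**Figure D4:**
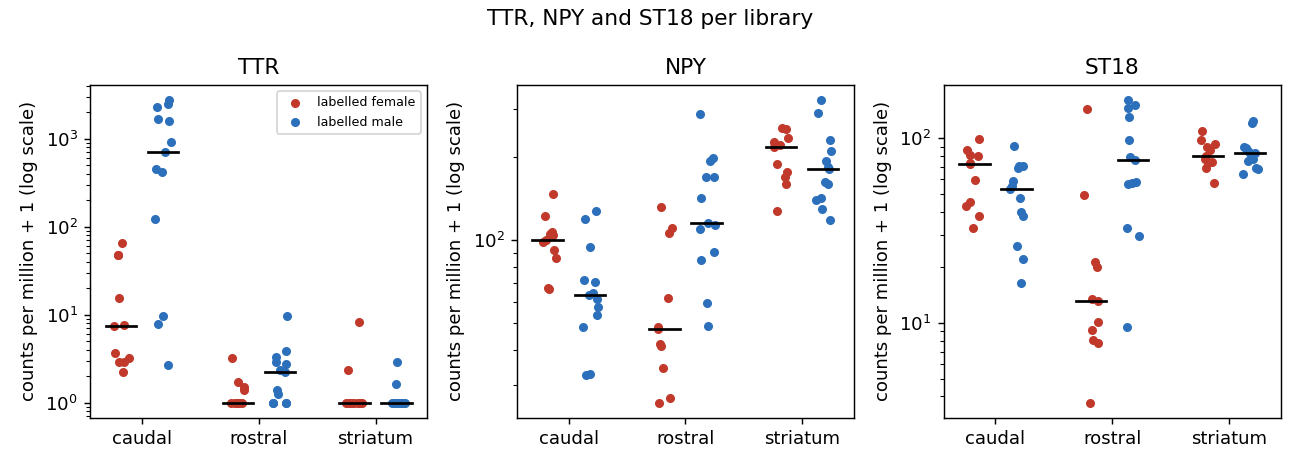
Each point is a library, with CPM plus 1 of TTR, NPY and ST18 on a log axis by region and sex label; black lines are medians. Caudal TTR counts have a median of 2295 in males and 17 in birds labelled female, and birds 8, 261 and 262 are the males at 5, 24 and 25 counts.

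In lists other than the Z list, few genes differed by sex in caudal hippocampus. HSD17B4 (0.74), GRIN3A (0.70) and HOMER1 (0.43), all on the Z sequence, rose in males with TTR and TF. The choroid plexus list had 1 riser of 8 genes (2 adjusted over the list alone; median -0.07 while the mean was 0.82 and camera positive, adjusted p = 0.610). CYP19A1 was at 1.02 ± 0.31 (adjusted p = 0.0744; it passed with DESeq2 and without bird 8, 13 or 15), DRD1 at 0.26 ± 0.12 (adjusted p = 0.322), NR3C1 at 0.08 ± 0.10 (adjusted p = 0.780), NR3C2 at -0.20 ± 0.08 (adjusted p = 0.251) and EGR1 at -0.02 ± 0.15 (adjusted p = 0.971). No list other than the Z list passed camera. The count of 42 other genes rested on single birds: it was 25, 25, 122, 81, 27 and 24 without bird 1, 6, 8, 14, 16 or 261, and 41 without bird 260. It was 1 when the library mean of the choroid plexus list was a covariate, an alternative chosen after seeing the data whose list holds TTR itself, and 19 with the myelin covariate, and with the former TF turned to -0.012. DESeq2 called 102.

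In rostral hippocampus more genes outside the sex chromosomes differed. CPAMD8 (2.09), STC2 (1.93), RGS22 (1.86), the Notch target HES5 (1.80), COL5A1 (1.78), ANXA2 (1.78), NHLH2 (1.48) and MLPH (1.45) were higher in males. FSTL4 (-1.66), the retinoic acid enzyme ALDH1A2 (-1.51), DACH2 (-1.50), CDH22 (-1.44), KL (-1.42), DACH1 (-1.30), CPNE4 (-1.22) and THSD7A (-1.19) were lower. NPY, a peptide of GABAergic neurons, was at 132 ± 65.2 CPM in males (SD, n = 13) and 59.4 ± 36.7 in birds labelled female (SD, n = 11), a log2 fold of 1.16 ± 0.29 (adjusted p = 0.0167). In all 476 of 9003 genes changed: 208 on the Z sequence, 6 on the W sequence (of 6 that passed the filter), all lower in males, and 262 others, 93 higher and 169 lower in males. The others were 469 with DESeq2 and 493 with bird as a random effect, where the total was 757.

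Of 16 GABAergic genes 2 rose in rostral hippocampus of males, NPY and SST (0.84), and 2 fell, among them CALB2 (-0.67) (2 and 3 adjusted over the list alone; camera adjusted p = 0.0631). Of 26 medium spiny neuron genes GPR6 (0.66) rose and SP9 (-0.45) and MEIS2 (-0.60) fell (1 and 11 adjusted over the list alone; median -0.32, camera adjusted p = 0.000561; adjusted p = 0.127 with an estimated correlation). Of 29 glutamate and GABA receptor genes GRIN3A (1.00), on the Z sequence, and GABRA5 (0.78) rose and 3 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.00134; adjusted p = 0.109 with an estimated correlation). Of 29 pallial genes ZBTB20 (0.96) and NFIB (0.48), on the Z sequence, rose and SATB1 (-0.75) fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0833). FABP7 (1.21) and HSD17B4 (0.90) rose and EGR3 (-0.52) fell. NR3C1 fell (-0.46 ± 0.14, adjusted p = 0.0486), a call lost in 22 of 33 alternatives, while NR3C2 (0.29 ± 0.13, adjusted p = 0.209), EGR1 (-0.42 ± 0.18, adjusted p = 0.180), DRD1 (-0.32 ± 0.12, adjusted p = 0.114) and CYP19A1 (1.32 ± 0.53, adjusted p = 0.151) did not pass. The calls of MLPH, HES5, RGS22, CALB2, SATB1, DACH2 and STC2 were lost in 24, 20, 18, 18, 17, 15 and 14 of the 33, and those of the other genes named here in at most 7. Without bird 22, NR3C2 and DRD1 passed. The count of 262 other genes was 167, 475, 153, 151, 123, 149, 711, 426 and 165 without bird 7, 8, 10, 14, 18, 19, 22, 261 or 262, and 306 without bird 260; the total was 310 without bird 18 and 951 without bird 22.

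In striatum few genes outside the sex chromosomes differed. DYRK4 (-2.35 ± 0.60, adjusted p = 0.0288) and ANKRD44 (-0.31 ± 0.08, adjusted p = 0.0499) were lower in males and TRPC4 (0.73 ± 0.18) higher, with the unnamed gene LOC100218152 (0.68 ± 0.18), which lies outside the naming rule and was added after its value was seen. DYRK4 was at 25.7 ± 62.2 CPM in birds labelled female (SD, n = 11) and 5.04 ± 2.50 in males (SD, n = 13), against 458 in caudal hippocampus. Its call ended without bird 2, 6, 9, 17, 20, 261 or 262, and without bird 6, a female, the log2 fold was -0.45 (adjusted p = 1). The striatum library of bird 6 had a mean log2 CPM of 5.78 over the pallial glutamatergic list, where the other striatum libraries had at most 4.72. Of 32 alternatives the call was lost in 12 for DYRK4, 22 for ANKRD44 and 6 for TRPC4. The 3 genes called in lists other than the Z list, HSD17B4 (0.89), GRIN3A (0.76) and NFIB (0.56), lie on the Z sequence. DRD1 (0.03 ± 0.08), DRD2 (0.09 ± 0.16), NR3C1 (-0.13 ± 0.12), NR3C2 (-0.02 ± 0.11) and EGR1 (-0.02 ± 0.14) all had an adjusted p of 0.999, and no list but the Z list passed camera. In all 148 of 8750 genes changed: 137 on the Z sequence, 7 on the W sequence (of 7 that passed the filter) and 4 others, 2 higher and 2 lower in males. Scaling on genes outside the sex chromosomes gave 3 and 1 of the others. The 4 others were 1 with limma voom, 8 with DESeq2 and 18 with bird as a random effect. Without bird 260 the counts were 226 in all and 8 others; the 4 others became 2 without bird 2, 6, 8, 13, 17, 18, 19, 22, 261 or 262 and 7 without bird 11.

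Calls outside the sex chromosomes overlapped little between regions. PSMA4 fell in males in both hippocampal parts and ANKRD44 in rostral hippocampus and striatum, and no other gene outside the sex chromosomes was called in a pair of regions. Independent lists would share 0.504 falling genes between the hippocampal parts and 0.0404 between rostral hippocampus and striatum.

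Whether the sex difference itself differed between regions was tested as an interaction. Between the hippocampal parts the smallest p was that of NPY, whose males minus females difference was lower in the caudal part (log2 -1.87 ± 0.28, adjusted p = 0.000117), followed by those of DLK1 (-1.46 ± 0.22), ST18 (-2.56 ± 0.46), KCTD6 (-0.78) and CDH22 (2.54). In caudal hippocampus NPY was at 66.0 ± 29.3 CPM in males (SD, n = 13) and 99.2 ± 25.98 in birds labelled female (SD, n = 11), a difference that did not pass there (log2 -0.59 ± 0.19, adjusted p = 0.121). In all 240 of 10445 genes passed, 141 with a more male-biased difference in the caudal part and 99 with a less male-biased one. Of 29 medium spiny neuron genes SIX3 (1.53), MEIS2 (0.65) and DRD1 (0.59) rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.000424; adjusted p = 0.151 with an estimated correlation). KL (3.11), SLC13A4 (2.95), TAGLN (2.32), TF (1.97), GABRD (1.06), MEF2C (0.93), GRIK4 (0.71), EGR3 (0.64) and NR3C1 (0.56) were more male-biased in the caudal part, and FOXJ1 (-2.66), FABP7 (-1.55), COL4A1 (-1.41), GPER1 (-1.33), GABRA5 (-1.32), ZBTB20 (-1.04) and LHX2 (-0.75) less so. Of 30 alternatives, the call was lost in 23 for LHX2, 19 for COL4A1, 17 each for NR3C1, DRD1 and GRIK4, 16 for EGR3, 14 for MEIS2, 12 for MEF2C, 10 for GPER1, 8 for SIX3 and 6 for GABRD, and in 15 and 6 of 29 for SLC13A4 and TAGLN. The count of 240 was 144 without the block, from 76 to 145 without bird 1, 2, 3, 6, 7, 9, 10, 14, 17, 18, 19 or 20, and 598, 406 and 481 without bird 8, 11 or 22.

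Between caudal hippocampus and striatum 0 genes passed the interaction test of edgeR, with 456 at an unadjusted p under 0.05; limma voom gave 0, edgeR without the bird block 0 and DESeq2, run only without bird terms, 2. Between rostral hippocampus and striatum 4 passed, ST18 (2.15 ± 0.46), NPY (1.39 ± 0.27), ZBTB20 (1.18 ± 0.24) and LOC100232212 (1.44), a hexokinase gene outside the naming rule that was added after its value was seen, all more male-biased in rostral hippocampus. The calls of ST18, ZBTB20 and NPY were lost in 24, 19 and 17 of 30 alternatives. There the medium spiny neuron list was lower (median -0.35, 0 of 29 genes called, 0 and 1 adjusted over the list alone, camera adjusted p = 0.000642, and adjusted p = 0.135 with an estimated correlation), as was the glutamate and GABA receptor list (median -0.08, 0 of 30, 1 and 4 adjusted over the list alone, camera adjusted p = 0.0292, and adjusted p = 0.135 with an estimated correlation). Neither list passed fry (adjusted p = 0.178 for each). The count of 4 was 0 without bird 1, 2, 3, 4, 7, 9, 10, 12, 15, 16, 18, 19, 20 or 262, 1 without bird 13 or 14, 2 without bird 6 and 103, 61 and 7 without bird 22, 8 or 261. The count of 0 between caudal hippocampus and striatum became 1 without bird 262.

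Birds of one sex also differed from each other at levels shared by their 3 regions. CENPE, a kinesin of the centromere, had per bird means from 0 to 40.6 CPM among birds labelled female and from 0 to 49.6 among males (F = 45.9, adjusted p = 3.52e-21). FCHSD2 (16.4 to 78.6 CPM in birds labelled female and 14.4 to 94.9 in males), AGT, the gene of angiotensinogen (24.5 to 102 and 8.85 to 122), and FEZ1 (30.1 to 224 and 126 to 230) followed. HNRNPK on the Z sequence came next, with 160 to 215 CPM in males and 83.2 to 136 in the birds labelled female other than bird 260, which had 248. In all 1162 of 10445 genes passed, 101 on the Z sequence, 30 on the W sequence and 1031 others. With bird 260 left out, an alternative chosen after seeing the data, 907 passed, of which 24 lay on the Z sequence, 1 on the W sequence and 882 elsewhere, so most calls on the sex chromosomes rested on that bird. The count was 324 with the hippocampal libraries alone and 1287 without bird 11.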

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

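The tests of bird 260, of depth as the whole cause for TTR and of the male component as the whole cause in rostral hippocampus were chosen after the results were seen, as were the reading of KL and the allowances for spread and low levels; the other tests were set before.

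The sex difference itself differed between the hippocampal parts in 240 genes by the interaction test, with NPY (-1.87), DLK1 (-1.46), ST18 (-2.56), KCTD6 (-0.78) and CDH22 (2.54) first. Of 40 random regroupings the highest other count was 0, which argues against chance as the source of 240 calls (1 regrouping, the real one, was as large). The regroupings bear on chance alone. A difference in where the rostral pieces were taken, left open below for the sexes, was not tested for these calls. In rostral hippocampus ST18 ranged from 11 to 590 counts in birds labelled female and from 33 to 726 in males. Between rostral hippocampus and striatum the sex difference differed in 4 genes, among them ST18 (2.15), NPY (1.39) and ZBTB20 (1.18), against a highest other count of 1 in 40 regroupings. Being the largest of 40 is the most this test can show. The count of 4 was 1 with limma voom, 2 without the block and as low as 0 with a bird left out. Chance is therefore not excluded for these 4 calls. For caudal hippocampus against striatum, where the real count was 0, all 40 regroupings had to be as large, so they decide nothing about chance; the highest of them called 430 genes and their median was 0, and what that 1 regrouping follows was not tested.

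In each of the other comparisons only 1 regrouping, the real one, was as large. This argues against chance for striatum against hippocampus and for the differences among birds. It does so too for the genes outside the sex chromosomes in the hippocampal parts. The real counts and the highest others were 4765 and 2022 for caudal against rostral hippocampus, 6537 and 0 for striatum against hippocampus, both of 40, and 238 and 13, 476 and 1, and 148 and 0 for the sexes in caudal hippocampus, rostral hippocampus and striatum, of 100. The totals of the sexes hold the Z and W genes, of which a grouping that mixes the sexes had to call fewer. These totals therefore decide nothing about chance. For genes outside the sex chromosomes the real counts and the highest others were 42 and 13, 262 and 1, and 4 and 0. The 4 calls in striatum were 1 with limma voom and as low as 2 with a bird left out. Chance is therefore not excluded for them. For differences among birds the real count and the highest other were 1162 and 5 of 40.

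The 3 libraries of bird 260, labelled female, held no CHD1W count. Low depth is argued against, since 104, 144 and 181 CHD1W counts were to be had at their depth (lowest 104). A swap with a male of this series is argued against too, as 0 libraries labelled male reached the lowest CHD1W count of the other females. A wrong label may be the cause: 2 of the 3 libraries had Z levels within the male range, and the third, caudal one, at -0.61, lay below the lowest male (-0.55) by less than the SD of the males (0.0618) and far above the other females (-1.42 to -1.13). The test as first written asked for all 3 within the range, which was not met. The allowance for spread was made after the value was seen, so that test by itself decides nothing. W CPM was 26.6, 28.0 and 22.96, where the other females had at least 1779. Z levels were -0.61, -0.50 and -0.55, where the other females had at most -1.08. These values argue against the label female for all 3 libraries, and how the label arose was not tested.

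TTR was higher in male caudal hippocampus, and depth as the whole cause is argued against, since mean total counts of males were 1.09 times those of birds labelled female while TTR, scaled for depth, differed by a log2 fold of 5.83 ± 0.93. Choroid plexus in some caudal pieces would carry its other genes along; their median correlation with TTR within the sexes was 0.0733 over 7 listed genes (bootstrap interval -0.074 to 0.365), under the bound of 0.2 set beforehand, which by itself counts against this source. That bound was poorly chosen, as was seen only afterwards, because 4 of the 7 genes averaged under 10 CPM and PROM1 and AQP1 were already at 125 and 28.2 CPM on average, so choroid plexus could still be the source and cannot be told apart here. KL, the highest of the 7 (the others had r of -0.118 to 0.337) and singled out for that, decides nothing by itself (r = 0.642, permutation p = 0.00118; rho = 0.514, p = 0.0109; r = 0.541 without the 2 libraries farthest in TTR; adjusted over 8 relations p = 0.00944 for r and 0.0872 for rho), while a smaller part of depth stays open with r = 0.283 (-0.197 to 0.614; permutation p = 0.179; rho = 0.167, p = 0.434; r = 0.166 without 2; adjusted p = 0.477 for r). A difference between the sexes is untested beyond the comparison itself.

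In rostral hippocampus 262 genes outside the sex chromosomes differed by sex. A larger share of myelin is argued against, since 289 genes were called with the myelin covariate, and so is the doubted label of bird 260, since 306 were called without it. Part of the pattern is consistent with a difference in where the rostral piece was taken: the log2 folds of the called genes correlated at 0.729 across genes, which are not independent replicates, with the main axis of variation among males alone, but at 0.351 over all 8565 tested genes outside the sex chromosomes, and that axis may equally be biological. That axis as the whole cause is argued against, because 207 genes were called with it as a covariate. The axis holds 22.5% of the variance among males and was not shown to measure position. Position as the whole cause therefore stays open. A biological sex difference remains open.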

How the results depend on the processing

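The choroid plexus and male component covariates, the fits without bird 260 or 11 in the bird test, and leaving out birds in the interactions were chosen after seeing the data. Region counts stayed within 1.5 times of 4765 and 6537 under every alternative run (4488 to 5072 and 6403 to 6584 when each bird was left out; 4366 and 5977 with no replicate block). For sex in caudal hippocampus the total was 202 to 321 with each bird left out and 150 with the choroid plexus covariate; the other 42 genes became 24 to 122, 19 with the myelin covariate, 1 with the choroid plexus covariate and 102 with DESeq2. In rostral hippocampus the total was 310 to 951 and 757 with bird as a random effect; the 262 others became 123 to 711, 493 and, with DESeq2, 469. In striatum the total was 136 to 226; the 4 others became 2 to 8, 1 with voom, 8 with DESeq2 and 18 with the random effect. With no replicate block the interaction counts 240 and 4 became 144 and 2, and the block changed no other call of a count. Leaving out each bird gave 76 to 598, 0 to 1 and 0 to 103 for the 3 interactions. With birds 1 to 22 the count of caudal hippocampus against striatum was 1 and that of rostral hippocampus against striatum 2; DESeq2 without bird terms gave 2 for the former, where edgeR without the block gave 0, and for the latter no filter gave 7 and voom 1. The bird test gave 324 with the hippocampal parts alone. Among the list tests of all comparisons, fry, which does not set a list against the other genes, passed 22 that camera did not and lost 2 camera calls. An estimated correlation lost 7 camera calls and added 0. Z medians were 0.67 to 0.77, 0.64 to 0.74 and 0.64 to 0.75 with each bird left out, highest without bird 260, and 0.53 in rostral hippocampus by the symbol list alone. With the choroid plexus covariate OTX2 (-1.07) and TF (-0.96) reversed between the hippocampal parts and TF (-0.012) between the sexes in caudal hippocampus; the list of that covariate holds OTX2. Apart from these settings' own construction, the cause was not tested. No paired analysis was possible because no bird is in both sexes, for the sex comparisons. Of the named genes' values, 5847 kept direction and call with a bird left out, 494 lost the call and 13 gained one; under the other alternatives 2116 kept both, 147 lost and 5 gained the call, and 3 reversed. At these depths and bird numbers 4.48% of simulated 1.5-fold and 60.6% of 4-fold changes were recovered in the interaction of the hippocampal parts. The simulated spread there took in the differences between regions, so the real fit may recover other shares.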

Other observations

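The genes below were found by the bird test and then set out per bird after their values were seen.

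CENPE counts were 0 to 7 in all 3 regions of some birds and 19 to 221 in all 3 regions of the others, with no bird between. AGT was low in all 3 regions of bird 8, a male, at 15 to 45 counts, where the median of males was 228 in caudal hippocampus, 394 in rostral hippocampus and 219 in striatum. Bird 260 had the lowest AGT count of the birds labelled female in each region, at 48, 98 and 116, and the lowest FCHSD2 count in caudal (28) and rostral hippocampus (67). FEZ1 ranged from 57 to 1034 counts in rostral hippocampus of birds labelled female and from 454 to 1174 in males. No explanation was tested for these genes.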
